A study of Homo sapiens with 7 samples.

How the data were processed

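RNA sequencing of polyadenylated RNA was deposited for 7 libraries from 2 human osteosarcoma cell lines, 143B and MG63. The lines had been treated for 48 h with vehicle or with an inverse agonist, a compound that lowers the basal activity of a receptor. The 143B line had 4 libraries (control, GSK805, XY018 and SR2211) and the MG63 line had 3 (control, GSK805 and XY018). Each group held 1 library. The labels give no dose for any compound. Every value column was matched to its sample by the line and compound in its name, and the column named for DMSO in the 143B table was taken as the control of that line.

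The deposited table for 143B holds FPKM values (fragments scaled for transcript length and library depth) as computed by the authors, rounded to 2 decimals. It lists 19314 genes, of which 16610 have values and 2704 have none in any library. The deposited table for MG63 holds expected counts, which are estimated read counts per gene and not whole numbers, for 16447 genes, together with FPKM and TPM (transcript abundance scaled to the same total in each library) columns that the authors derived per library. Both deposited tables also carry log2 ratios by the authors. In 143B these equal the log2 ratio of the FPKM columns, and in MG63 the log2 ratio of the counts without scaling for depth. The authors' columns of false discovery rates exceed 1 for part of the genes and were not used. The analysis had been planned for counts or FPKM in both lines, and only MG63 came with counts.

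The descriptions of the upstream steps differ. The series design names SOAPnuke, HISAT, Bowtie2 and RSEM with a TruSeq preparation on a BGISEQ instrument. The processing notes per sample name TopHat2, HTSeq and DESeq2 with the builds GRCh38, hg19 and hg38, and the extraction notes name a NEBNext Ultra Directional kit and Illumina sequencing. Gene positions in the MG63 table match GRCh38, and positions are given on that build, counted from 1. The tables could not decide between the other descriptions.

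In 143B, 28 gene symbols had been turned into dates, so genes were joined by their Entrez identifiers; 15415 genes had values in both tables. The tables were normalized separately and levels were not compared between them. For 143B the value per gene was the log2 of FPKM plus a pseudocount of 0.5, and a gene entered a comparison with an FPKM of at least 1 in the larger of the compared libraries. For MG63, the counts were scaled with the trimmed mean of M values (TMM) in edgeR over the 3 libraries, the value was the log2 of the scaled counts (CPM) plus 0.5, and a gene entered with at least 50 counts in the larger library. The difference of a gene was the log2 ratio of treated to control, or of compound to compound. With 1 library per group there was no replicate error and no test of a difference, and no p-value is given. Genes at least 2-fold higher or lower were counted as a size. In MG63 the exact 95% counting interval of the ratio, from rounded counts and without the pseudocount, also had to exclude no difference, which removed 0 genes. Such intervals cover counting error alone.

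Expected counts totalled 20935440 in the MG63 control, 21372161 with GSK805 and 21322841 with XY018, and the TMM factors were 1.01, 1.00 and 0.984. The 143B table gives no counts and no depth. The steps between its lowest FPKM values, set against the transcript lengths, gave an estimate of 16.9 M reads with GSK805, 17 M with SR2211, 16.65 M with XY018 and 16.95 M in the control. At these depths 88.4% of 405 low values in the control lay within 0.15 of a whole read, against 45% with shuffled lengths. No counting interval was taken from these estimates.

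Gene lists were written before the data were examined, 55 lists with 1160 entries. They covered the nuclear subunits of the respiratory complexes and ATP synthase and their assembly factors; the mitochondrial ribosome, biogenesis, dynamics and unfolded protein response; the TCA cycle, glycolysis, fatty acid, cholesterol, phospholipid and glutamine metabolism; LXR targets, the circadian clock and ROR-linked nuclear receptors; stress, hypoxia, xenobiotic, p53, apoptosis and ferroptosis genes; the cell cycle, DNA repair, ribosome biogenesis and ribosomal proteins; interferon, antigen presentation, NF-kB and immediate early genes; bone, matrix, junction, TGF-beta, YAP, Wnt, autophagy and growth factor genes; and markers of other cell types. Per comparison, each list with at least 5 measured members (4 for complex II) was given its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below the percentile 2.5 or above 97.5. This percentile describes the libraries at hand and carries no replicate error. No list held genes picked from these libraries. For 5 lists too few members were measured in every comparison, those of mitochondrially encoded subunits, the Th17 programme, and haematopoietic, endothelial and neural markers; mitochondrially encoded genes are in neither table and were not analysed here.

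Named genes followed a rule fixed at the same stage: the 8 genes with the largest smallest difference each way over all compounds of a line; the 4 highest and 4 lowest per compound and line; up to 4 members with the largest mean difference per list; the 6 genes each way with the largest smallest difference over GSK805 and XY018 in both lines; the 4 each way per pair of compounds; and genes of the ROR receptor family. A few genes that the rule selects are not reported here. Except for list members and the ROR genes, they needed a mean FPKM of 2 or a mean count of 100. Where a gene shared at least 50% of its 31-base words with another gene of the tables, its value rests on how reads were divided between copies, and it is named as uncertain.

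Sharing between comparisons was described by Pearson and Spearman correlations across genes and by overlaps of the genes past 2-fold. Comparisons within a line share their control library, so libraries without any difference were simulated against the same control, with counting error alone and with added variation, to show the correlation that sharing alone gives. The added variation was 3.62% for both lines. It was taken from the SR2211 and control libraries of 143B, over genes with at least 500 estimated reads. Added after the data had been seen, overlaps were simulated with the differences of a compound shuffled among genes of like level, in 200 draws with the control library in common. The rankings over all compounds of a line were given such counts as well. Simulated data with known differences were drawn from the MG63 control counts at the depths of the control and GSK805 libraries, with counting error alone. There 49 of 50 genes set 2.5-fold apart and 50 of 50 set 4-fold apart were past 2-fold, and 0 of the genes left alike were. Of 40 random lists without a shift 1 stood apart, and 40 of 40 lists shifted by 0.2 on the log2 scale did. Ratios in the real libraries spread more, so these numbers do not carry over to them. With GSK805 in MG63, bone genes had a median of 0.43 and did not stand apart (percentile 96.1).

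The alternatives were total-count and median-of-ratios scaling, the deposited FPKM and TPM in MG63, pseudocounts of 0.1 and 2, no filter on low values, stricter floors of 5 FPKM or 200 counts, sizes of 1.5-fold and 4-fold, means in place of medians, and random lists without matching. Random lists matched also on transcript length, and counts without genes that share sequence, were added after the data had been seen. All genes of both tables are protein-coding entries. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.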

Results

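Transcript levels were measured by RNA sequencing in 2 osteosarcoma cell lines, 143B and MG63, after 48 h with inverse agonists. The series title asks whether a nuclear receptor stimulates mitochondrial oxidative phosphorylation in this tumor. The 143B line was treated with GSK805, XY018 or SR2211, and MG63 with GSK805 or XY018, each beside a vehicle control of its own line. Each of the 7 groups held 1 library, so no difference below could be checked against replicates, and every value is the ratio of a pair of libraries. The labels give no dose, so differences between compounds cannot be set at matched doses. Depth was 20935440 to 21372161 expected counts per library in MG63 and an estimated 16.65 to 17 M reads in 143B, where the table holds FPKM alone.

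**Figure D1:**
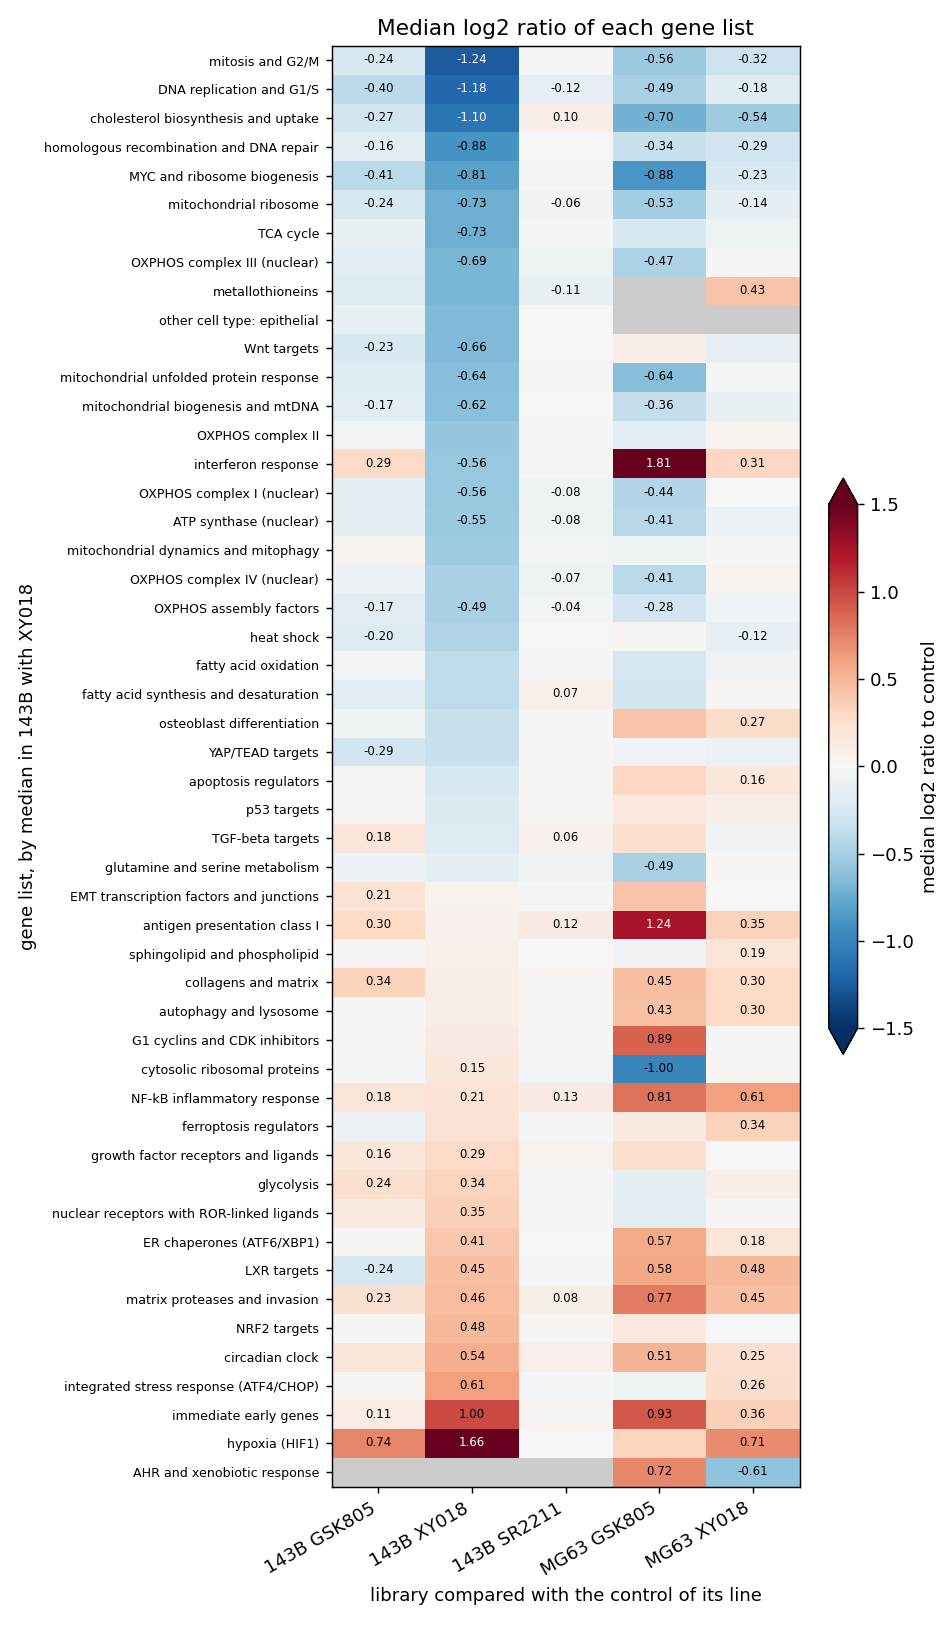
Median log2 ratio to control of each gene list (rows) in the 5 comparisons (columns), with a value printed where the list stood apart from random lists of like expression and grey where too few members were measured. Colour is clipped at 1.5 either way. The hypoxia list had its highest median with XY018 in 143B (1.66), the interferon list with GSK805 in MG63 (1.81).

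The subunits of oxidative phosphorylation, the machinery that makes ATP in mitochondria, were lower with XY018 in 143B and with GSK805 in MG63. Of 78 measured nuclear subunits, 76 lay below control with XY018 in 143B, 34 were at least 1.5-fold lower and 5 at least 2-fold lower, and the median log2 ratio was −0.55. With GSK805 in MG63, 74 lay below control, 22 were at least 1.5-fold lower and 3 at least 2-fold lower, with a median of −0.41. GSK805 in 143B gave a median of −0.12 and SR2211 one of −0.07, with 66 and 69 subunits below control and 0 at 1.5-fold. With XY018 in MG63 the subunits were spread around the control, 38 below and 40 above, with a median of 0.00.

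By complex, XY018 in 143B gave medians of −0.56 for the 37 subunits of complex I, −0.58 for the 4 of complex II, −0.69 for the 9 of complex III, −0.49 for the 12 of complex IV and −0.55 for the 16 of ATP synthase. Among the lowest were NDUFS6 of complex I at −1.16, CYC1, the cytochrome c1 of complex III, at −1.13, and ATP5MC1, a ring subunit of ATP synthase, at −1.27. The 2 subunits above control were COX7A2L, which shapes supercomplexes, at 0.85 and UQCRC1 at 0.11. GSK805 in MG63 gave −0.44, −0.16, −0.47, −0.41 and −0.41 for the same complexes, with ATP5MC1 at −1.43, ATP5F1D at −1.42, NDUFA3 at −1.08 and CYC1 at −0.89. GSK805 in 143B gave −0.13, −0.04, −0.16, −0.09 and −0.14, and SR2211 gave −0.08, −0.03, −0.07, −0.07 and −0.08. XY018 in MG63 gave 0.01, 0.05, −0.02, 0.05 and −0.09, where the signs for complexes I, II and IV flip with the scaling.

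Set directly against each other, the subunits were higher with GSK805 than with XY018 in 143B (median 0.44, 22 subunits at least 1.5-fold higher) and lower with GSK805 than with XY018 in MG63 (median −0.45, 21 subunits at least 1.5-fold lower). Against SR2211 in 143B, XY018 gave −0.48 and GSK805 −0.04. Among random lists of like expression the 78 subunits lay at percentile 0 with XY018 in 143B and GSK805 in MG63, 1.89 with GSK805 in 143B, 0 with SR2211 and 48.7 with XY018 in MG63. In MG63 with GSK805, short transcripts were lower and long ones higher across all genes, with median log2 ratios of −0.34 in the shortest and 0.42 in the longest of 5 equal groups. In deposited TPM the medians there were −0.25 for complex I, −0.01 for complex II, −0.27 for complex III, −0.21 for complex IV and −0.22 for ATP synthase. With GSK805 in MG63, complexes I, III and IV and ATP synthase no longer stood apart from random lists matched also on length (percentiles 7.95, 19.6, 40.4 and 20.95), nor did complex III and ATP synthase with XY018 in 143B (2.76 and 3.23).

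**Figure D2:**
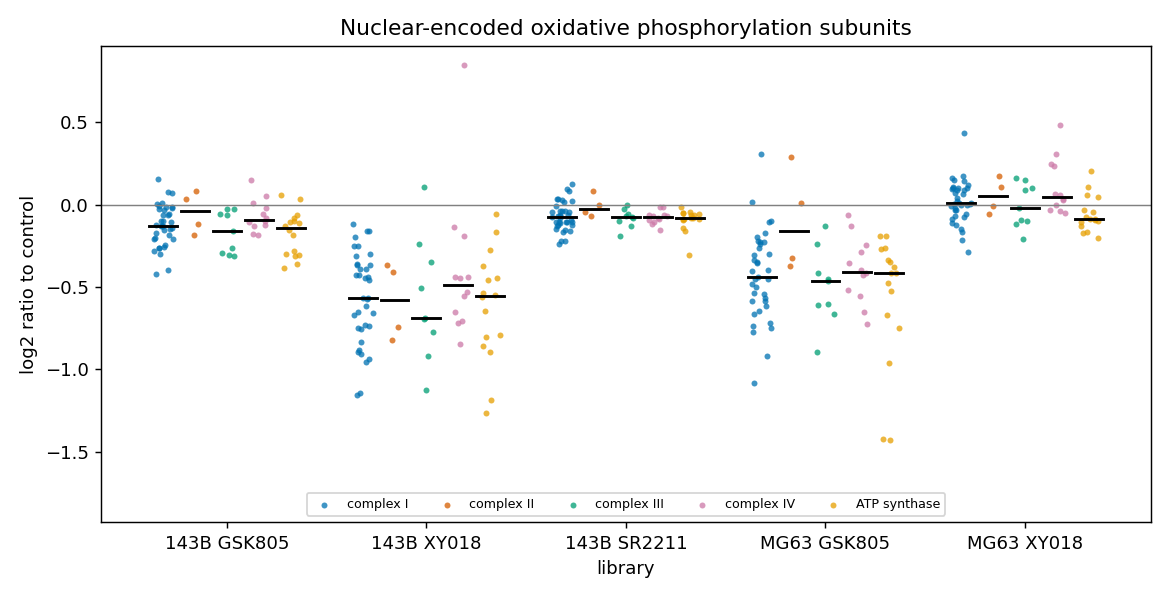
Log2 ratio to control of each nuclear subunit of oxidative phosphorylation (points), by complex, in the 5 comparisons; black bars are the medians of each complex. The points lie mostly below 0 with XY018 in 143B and GSK805 in MG63 (medians over all 78 subunits −0.55 and −0.41) and around 0 with XY018 in MG63, where the signs for complexes I, II and IV flip with the scaling.

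The comparison of XY018 with control in 143B had the widest spread of the 5. Of 11950 genes, 802 were at least 2-fold higher and 888 at least 2-fold lower. Genes of matrix breakdown, hypoxia and stress were among the highest, and genes of cell division and cholesterol synthesis among the lowest. MMP10, a stromelysin that degrades matrix (chromosome 11, 102770502 to 102780628), went from an FPKM of 0.58 in the control to 51.1, a log2 ratio of 5.58. STC1, the secreted glycoprotein stanniocalcin (chromosome 8, 23841929 to 23854806), went from 15.9 to 382 (4.54). MMP3, another stromelysin, was at 4.23, and MMP13, a collagenase, at 4.21. At the other end CCN2, a matricellular growth factor also known as CTGF (chromosome 6, 131943656 to 132084388), went from 73.1 to 7.90 (−3.13). PLAU, the protease urokinase, went from 262 to 41.9 (−2.63), and ERVMER34-1, an endogenous retroviral envelope gene, was at −2.71. U2AF1L5 was also among the lowest 4, but shares nearly all its sequence with another gene.

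Hypoxia genes gave the highest list median with XY018 in 143B, 1.66, with 14 of 19 members at least 2-fold higher. NDRG1 was at 3.76, ANGPTL4, an inhibitor of lipoprotein lipase, at 3.17, and BNIP3, a mitophagy receptor, at 2.80. Glycolysis genes had a median of 0.34, with 5 of 23 at least 2-fold higher, among them the glucose transporters SLC2A3 (2.15) and SLC2A1 (1.75) and the enolase ENO2 (2.10). Immediate early genes had a median of 0.996 and 13 of 26 were past 2-fold, including NR4A2 (3.84), KLF4 (3.28) and FOSB (2.90). In the integrated stress response, the programme of the transcription factor ATF4, 14 of 36 genes were at least 2-fold higher (median 0.61), with DDIT4, an inhibitor of mTOR, at 2.51, ATF3 at 2.36 and INHBE at 2.29. Genes of the unfolded protein response of the endoplasmic reticulum had a median of 0.41, with DNAJB9 at 2.61 and HERPUD1 at 2.53. NRF2 targets, which answer oxidative stress, had a median of 0.48, with the reductase AKR1C1 at 3.13 and the cystine transporter SLC7A11 at 1.80. Of 18 matrix proteases 6 were past 2-fold higher and 1 lower, with a median of 0.46.

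Genes of DNA replication and mitosis were lower with XY018 in 143B, while G1 cyclins and CDK inhibitors, with a median of 0.12, did not stand apart. Of 34 genes of DNA replication 22 were at least 2-fold lower and 33 at least 1.5-fold lower, with a median of −1.18; MCM6 of the replicative helicase was at −1.79 and MCM10 at −1.67. Of 35 mitosis genes 25 were at least 2-fold lower (median −1.24), including KIF20A (−1.81), CDC20 (−1.74) and CCNB1 (−1.73). Homologous recombination genes had a median of −0.88, with EXO1 at −1.45. Cholesterol synthesis and uptake had a median of −1.10 and 14 of 24 genes at least 2-fold lower, among them HMGCS1 (−2.20), ACAT2 (−1.93) and MVK (−1.87). The mitochondrial ribosome had a median of −0.73 with 26 of 40 genes at least 1.5-fold lower. TCA cycle enzymes also had −0.73, with fumarase, FH, at −1.25, and pyruvate carboxylase, PC, at 0.90. Ribosome biogenesis genes had −0.81, the mitochondrial unfolded protein response −0.64, mitochondrial biogenesis −0.62 and OXPHOS assembly factors −0.49. LXR targets, which export cholesterol, had a median of 0.45, with ABCG1 at 3.63 and ABCA1 at 1.87. Ribosomal protein genes had 0.15.

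Of the 49 lists with enough members 28 stood apart, 13 high and 15 low, where 2.45 lists of randomly drawn genes would. Genes of a list can move together, and 13 of 49 stood apart even with SR2211, nearest to the control. An excess over 2.45 is therefore no measure of the response to XY018. With length matched 24 of the 28 stood apart on the same side, without complex III, ATP synthase, the mitochondrial unfolded protein response (2.585) and ROR-linked nuclear receptors (97.3). The median of all genes was −0.12 here and −0.01 under median-of-ratios scaling, which gave 969 genes higher and 649 lower, so that the share higher among those past 2-fold was 47.5% in the first and 59.9% in the second. The balance of higher and lower genes therefore depends on the scaling.

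GSK805 against control in 143B gave fewer genes past 2-fold, 54 higher and 33 lower of 11831. Hypoxia genes were again the highest list, with a median of 0.74 and 4 of 19 at least 2-fold higher. ANGPTL4 (chromosome 19, 8363033 to 8374373) went from an FPKM of 4.63 to 30.8 (2.61), IL13RA2, a decoy receptor for an interleukin, was at 2.39, PTGS2, the inducible cyclooxygenase, at 1.92 and NDRG1 at 1.79. CCN2 was at −1.89 and PLK2, a polo-like kinase, at −1.74. Glycolysis genes had a median of 0.24, with ENO2 at 1.08, collagen and matrix genes 0.34, with the collagen hydroxylase P4HA2 at 1.1, and matrix proteases 0.23, with MMP1 at 1.21. Interferon genes had 0.29, with OASL at 1.44 and IFIT2 at 1.25, class I antigen presentation 0.30 and junction and mesenchymal genes 0.21.

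Among the lower lists with GSK805 in 143B, ribosome biogenesis had a median of −0.41, with RRS1 at −0.81 and MYC, which drives it, at −1.03. DNA replication had −0.40, YAP targets −0.29, with ANKRD1 at −1.49, cholesterol synthesis −0.27, with MVK at −0.83, mitosis −0.24 and Wnt targets −0.23, with the Wnt inhibitor DKK1 at −1.42. LXR targets had −0.24, with ABCA1 at −1.01. The mitochondrial ribosome had −0.24 and OXPHOS assembly factors −0.17, with the complex III chaperone BCS1L at −0.65. SULT1A3 and SULT1A4, near-identical copies of a sulfotransferase gene, lay at opposite ends and at 0 in part of the libraries, and U2AF1L5 was also among the lowest. Of 49 lists 23 stood apart, 11 high and 12 low. Longer transcripts were higher here too, with medians of 0.10 in the longest and −0.09 in the shortest of 5 equal groups. With length matched 21 of the 23 stood apart on the same side, without mitochondrial biogenesis (2.69) and growth factors (95.9). Another 2 lists then stood apart, the integrated stress response (97.9) and fatty acid synthesis (0.47).

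SR2211 in 143B lay nearest to the control. Of 11787 genes, 9 were at least 2-fold higher and 5 lower, and the SD across all genes was 0.16 on the log2 scale. Of these 14 genes, 10 share at least 50% of their sequence with another gene: SULT1A3, LIMS4, URGCP-MRPS24, TBC1D3I, NPIPA2 and TPTEP2-CSNK1E higher, and SULT1A4, LIMS3, SMIM11A and POC1B-GALNT4 lower. The other 4 were CCDC74A (1.1), TMEM74B (1.06), H2AC11 (1.0) and the metallothionein MT1M (−1.09); those of the 14 outside the rule for names were chosen after their values were seen. Of named genes below 2-fold, S100A4, a calcium-binding protein of motile cells, was at −0.88 and ACTA2, smooth muscle actin, at −0.78; MDP1, at 0.82, overlaps a readthrough gene that was lower and is uncertain.

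DNA replication genes had a median of −0.12 with SR2211, cholesterol synthesis 0.10, fatty acid synthesis 0.07, NF-kB targets 0.13, class I antigen presentation 0.12 and matrix proteases 0.08. None of these 6 lists had a member past 2-fold. Of 49 lists 13 stood apart, 6 high and 7 low, and with length matched 9 of them did. Complex IV, OXPHOS assembly factors (−0.04), the mitochondrial ribosome (−0.06) and metallothioneins (−0.11) then lay at percentiles 7.93, 13.7, 6.67 and 5.71. Glutamine and serine metabolism then stood apart in addition (0.915). Log2 ratios followed transcript length with SR2211 as well (Spearman 0.23). Over 6779 genes with at least 500 estimated reads, the robust SD between this library and the control was 0.093 on the log2 scale.

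All 3 ratios in 143B use the same control library, so a value that was off in the control gives a difference with every compound. Simulated libraries with unrelated responses and that control held a mean of 5.82 genes (upper end of the 95% range 11) as far upward as the 8 ranked here, so the 8 higher genes do not show a shared response; downward it was 1.70 (5). The genes with the largest shared difference upward were ANG, the ribonuclease angiogenin (at least 0.65 with each compound), KRT15 (0.86, 1.33 and 0.53 with GSK805, XY018 and SR2211) and LHPP (0.77, 0.56 and 0.57). ASB3 (0.53, 0.80 and 0.64) and MDP1 (0.58, 0.57 and 0.82) are uncertain, since the readthrough genes that overlap them, GPR75-ASB3 and NEDD8-MDP1, were lower with every compound and reads may have been divided differently between the entries. NPIPA2, MEF2B and LINC02210-CRHR1 belong to the same 8, with sequence shared with other genes. Downward they were MT1M (−1.01, −2.39 and −1.09), IMMP1L, a mitochondrial inner membrane peptidase (−1.15, −0.92 and −0.69), DKK1 (−1.42, −0.83 and −0.59), HMX2 (−0.57, −1.05 and −0.55) and PDF, the mitochondrial peptide deformylase (−0.62, −1.18 and −0.52). NEDD8-MDP1, NME1-NME2 and GPR75-ASB3, also among the lower 8, are readthrough genes that share sequence with their neighbours.

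Between compounds in 143B, 554 genes were at least 2-fold higher and 537 lower with GSK805 than with XY018, of 11952. ESM1, a secreted proteoglycan, and CCL2, a chemokine, were both 2.56 higher on the log2 scale with GSK805, and GRB14, an adaptor of the insulin receptor, 2.54. ABCG1 was at −4.19, MMP10 at −4.16 and the chemokine receptor CXCR4 at −4.03 in the same ratio. Mitosis genes were higher with GSK805 (median 1.04, 18 of 35 past 2-fold), as were interferon genes (0.83, 10 of 26), DNA replication (0.78) and cholesterol synthesis (0.77, 6 of 24), and immediate early genes (−0.98, 13 of 26), LXR targets (−0.77) and hypoxia genes (−0.75, 7 of 19) were lower. XY018 against SR2211 gave 749 genes higher and 942 lower of 12007, with MMP10 at 5.30, CXCR4 at 4.61, STC1 at 4.37, CCN2 at −2.94 and ERVMER34-1 at −2.75. Hypoxia genes had a median of 1.70 and mitosis genes of −1.24. GSK805 against SR2211 gave 31 higher and 27 lower of 11857, with ANGPTL4 at 2.53, IL13RA2 at 2.03, TNFRSF11B, the decoy receptor osteoprotegerin, at 1.71, PTGS2 at 1.65, PTCD1 at −1.79, CCN2 at −1.69 and PLK2 at −1.56. Hypoxia genes had 0.73 there and ribosome biogenesis −0.37. The copies SULT1A3, SULT1A4 and U2AF1L5 were also among the extremes of these pairs.

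GSK805 in MG63 was marked by antiviral and inflammatory genes. Of 11373 genes, 706 were at least 2-fold higher and 442 lower. RSAD2, the antiviral enzyme viperin (chromosome 2, 6865733 to 6898239), went from 142 to 4121 expected counts, a log2 ratio of 4.75 with a counting interval of 4.61 to 5.10. TRIM22, an antiviral ubiquitin ligase, went from 163 to 3599 counts (4.37), and SCARA5, a ferritin receptor, from 65 to 1528 (4.33). At the other end IAH1, an esterase, went from 189 to 5.02 counts (−3.68), PLD4 was at −3.33 and AOX1, aldehyde oxidase, at −2.93. TMED7-TICAM2, highest of all with 0 counts in the control, and EIF3CL, lowest, share nearly all their sequence with other genes.

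Interferon genes had a median of 1.81, and 31 of 36 were at least 2-fold higher, among them CXCL10 (3.14), MX2 (2.93) and CXCL11 (1.70). All 14 measured genes of class I antigen presentation were at least 1.5-fold higher and 9 at least 2-fold (median 1.24), with the peptide transporter TAP1 at 2.28 and HLA-F at 2.02. NF-kB targets had 0.81, with PTGS2 at 2.97, IL1B at 2.73 and LIF at 1.92. Immediate early genes had 0.93, with SPRY2 at 2.87. Matrix proteases had 0.77, with ADAM12 at 1.36. Matrix genes had 0.45, with the proteoglycan VCAN at 3.51, fibronectin, FN1, at 2.90, TNC at 2.22 and FBN1 at 2.08, but not apart with length matched (93.7). G1 cyclins and CDK inhibitors had 0.89, with CDKN1A at 1.67 and CCND1 at 1.39. LXR targets had 0.58, with ABCA1 at 1.35, endoplasmic reticulum chaperones 0.57, with SEL1L at 1.26, and the circadian clock 0.51, with BHLHE40 at 1.21.

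Ribosomal protein genes were lower with GSK805 in MG63, all 48 by at least 1.5-fold and 22 by at least 2-fold, with a median of −0.995. RPS2 went from 105300 to 37180 counts (−1.51) and RPSA was at −1.29. Ribosome biogenesis had a median of −0.88 with 10 of 27 past 2-fold, including BOP1 (−1.64), RRP9 (−1.57) and NOP56 (−1.28), and MYC was at −1.32. Cholesterol synthesis had −0.70, with MVK at −1.70 and DHCR7, which makes cholesterol in its last step, at −1.61. Mitosis had −0.56, with AURKB at −1.23, and DNA replication −0.49, with MCM2 at −1.13. The mitochondrial unfolded protein response had −0.64, with the chaperone TRAP1 at −1.36, the mitochondrial ribosome −0.53, with MRPL12 at −1.37, glutamine and serine metabolism −0.49, with PHGDH at −1.25, and OXPHOS assembly factors −0.28. In these libraries log2 ratios followed transcript length across genes (Spearman 0.43) and GC content (−0.32), so short and GC-rich transcripts tended to be lower.

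Of 48 lists 27 stood apart, 12 high and 15 low, where 2.4 lists of randomly drawn genes would. Genes of a list can move together, so that number is no yardstick for an excess. With length matched 21 of the 27 stood apart on the same side, without assembly factors (26.7). Another 3 lists then stood apart: hypoxia genes (median 0.34, percentile 98.0), apoptosis genes (98.2) and fatty acid synthesis (0.58). In deposited TPM the median of all genes was 0.21 and 1068 genes were higher against 219 lower (83.0% higher, against 61.5% here), so directions are relative to that shift; the medians were then 1.98 for interferon genes, −0.80 for ribosomal proteins and −0.51 for cholesterol synthesis.

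XY018 in MG63 gave 83 genes at least 2-fold higher and 29 lower of 11291. ABCA1, which exports cholesterol (chromosome 9, 104781006 to 104928155), went from 199 to 1101 counts, a log2 ratio of 2.42 with a counting interval of 2.27 to 2.71. GDF15, a stress-induced cytokine, was at 2.26 and MMP3 at 1.96. MYEOV was at −1.88, going from 103 to 20 counts, KRT80, a keratin, at −1.46 and FGF2, a fibroblast growth factor, at −1.35. TMED7-TICAM2 was the highest here too, and SLX1B and SERF1B, copies of other genes, were among the lowest.

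Hypoxia genes had the highest list median with XY018 in MG63, 0.71, with 7 of 20 at least 2-fold higher and 14 at least 1.5-fold. CA9, a carbonic anhydrase, went from 4 to 143 counts (3.41), NDRG1 was at 1.75, ANKRD37 at 1.51 and P4HA1 at 1.30. NF-kB targets had a median of 0.61, with LIF at 1.21 and IL1B at 1.12, LXR targets 0.48, with ABCG1 at 2.39, and matrix proteases 0.45, with MMP1 at 1.39. Immediate early genes had 0.36, class I antigen presentation 0.35, interferon genes 0.31, with RSAD2 at 1.58, collagen and matrix genes 0.30, bone genes 0.27, with BMP2 at 1.83, and the integrated stress response 0.26. Cholesterol synthesis had −0.54, with HMGCS1 at −1.05, the 1 of 23 genes past 2-fold, ACAT2 at −0.85 and FDPS at −0.69. Mitosis had −0.32, with CENPE at −0.88, homologous recombination −0.29, ribosome biogenesis −0.23, DNA replication −0.18 and the mitochondrial ribosome −0.14, with 0 members of the last 4 past 2-fold. Of 49 lists 25 stood apart, 17 high and 8 low, and log2 ratios hardly followed length (Spearman −0.02). With length matched 24 of the 25 stood apart on the same side, without heat shock genes (percentile 2.98).

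Both ratios in MG63 use the same control library too, and such simulated libraries held a mean of 1.23 genes as far upward as the 8 ranked here (upper end 4.03) and 2.53 as far downward (6). The genes with the largest shared difference upward were BMP2, a bone morphogenetic protein (3.27 with GSK805 and 1.83 with XY018), TMEM140 (3.76 and 1.62), BMP6 (2.52 and 1.61), RSAD2 (4.75 and 1.58), GDF15 (1.57 and 2.26), BATF2 (2.79 and 1.57) and ABCA1 (1.35 and 2.42), beside TMED7-TICAM2. Downward they were KRT80 (−2.61 and −1.46), FGF2 (−1.09 and −1.35), PTPRQ (−0.89 and −0.89), UACA (−0.95 and −0.87), PLK2 (−1.71 and −0.85), ACAT2 (−1.04 and −0.85), ALPK2 (−1.39 and −0.85) and ARSI (−0.95 and −0.85).

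Set directly against each other in MG63, 507 genes were at least 2-fold higher and 352 lower with GSK805 than with XY018, of 11370. RHOB, a small GTPase, was at 4.25 and SCARA5 at 3.64, and IAH1 was at −3.81, PLD4 at −3.21 and HHIP, which binds hedgehog ligands, at −2.66. SLX1B, BIVM-ERCC5 and EIF3CL, also at the extremes, share sequence with other genes. Interferon genes had a median of 1.39 with 27 of 36 past 2-fold, antigen presentation 1.01 with 8 of 14, and matrix proteases 0.64. Ribosomal proteins had −1.04 with 29 of 48 past 2-fold lower, LXR targets −0.91, ribosome biogenesis −0.75, hypoxia genes −0.55, glycolysis −0.47 and DNA replication −0.30.

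Between compounds of a line, log2 ratios to control went together across genes, which are not independent replicates, with a Pearson r of 0.57 for GSK805 and XY018 in 143B, 0.51 for GSK805 and SR2211, 0.15 for XY018 and SR2211, and 0.45 for GSK805 and XY018 in MG63. The shared control alone gave an r of 0.50 in simulated libraries without any difference, so these correlations do not by themselves show a shared response. The covariances were larger than the simulated 0.00514 in 143B and 0.00549 in MG63, at 0.117 for GSK805 and XY018 in 143B, 0.0238 for GSK805 and SR2211, 0.0162 for XY018 and SR2211 and 0.0866 in MG63. Simulated with added variation, the covariance was 0.00754 and 0.00808. In 143B the ratios with GSK805 and with SR2211 both followed transcript length (Spearman 0.27 and 0.23). The simulations held no such trend, which can add to the covariance of that pair. Of the genes past 2-fold, GSK805 and XY018 shared 33 higher and 17 lower in 143B and 35 higher and 10 lower in MG63. Simulated libraries with unrelated responses and the same control shared means of 7.23 and 3.69 in 143B and of 9.81 and 2.19 in MG63, and the upper ends of the 95% range of draws were 13 and 7.03 in 143B and 17 and 6 in MG63. The variation used here, 3.62%, came from SR2211 and the control in 143B, a pair that lay close together. A control that was off by more would raise the simulated values. An excess over them therefore does not by itself show a shared response.

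Between the lines, no library is shared. GSK805 gave a Pearson r of 0.46 across 10636 genes and XY018 0.47 across 10630 (Spearman 0.50 and 0.46), as 2 of 10 correlations computed between the 5 comparisons. The lines shared 19 higher and 5 lower genes past 2-fold with GSK805, where independent lists would share 2.05 and 0.748, and 41 higher and 5 lower with XY018, against 3.91 and 1.35. Sharing was not limited to matched compounds. XY018 in 143B and GSK805 in MG63 shared 139 higher and 113 lower, against 35.5 and 26.7 (r 0.39). GSK805 in 143B and XY018 in MG63 shared 5 and 0, against 0.228 and 0.0415 (r 0.27). Both GSK805 ratios also followed transcript length (Spearman 0.27 in 143B and 0.43 in MG63), which can add to their correlation. The ratio of GSK805 to XY018, which leaves the controls out, did not go together between the lines, with an r of −0.04 and a Spearman rho of −0.05 across 10667 genes; of the genes past 2-fold in both lines, 27 were higher in both, 23 lower in both and 62 opposite.

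**Figure D3:**
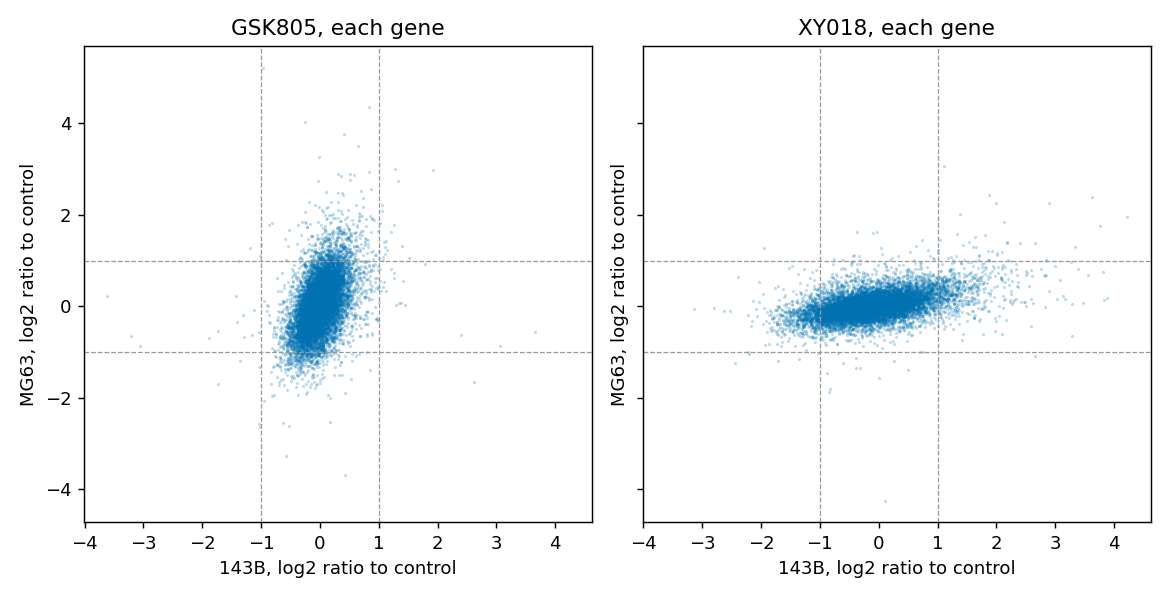
Log2 ratio to control of each gene in 143B (x axis) and MG63 (y axis), for GSK805 and for XY018; each point is a gene and dashed lines mark 2-fold. Pearson r across genes was 0.46 for GSK805 and 0.47 for XY018, and the spread was wider in MG63 for GSK805 and in 143B for XY018.

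Of 9653 genes compared with GSK805 and XY018 in both lines and past the floors on mean FPKM and mean count, 28 were at least 1.5-fold higher in all 4 comparisons and 5 at least 1.5-fold lower. The comparisons share a control within each line; with the genes past that size in each line as observed and the lines unrelated, 4.25 and 0.323 would be. The 6 with the largest smallest difference upward were ARRDC3, an arrestin-domain protein, RGS9, a regulator of G-protein signalling, PNRC1, a nuclear receptor coregulator, NDRG1 (chromosome 8, 133237171 to 133297304), WIPI1, which acts in autophagosome formation, and LIF, a cytokine. ARRDC3 had log2 ratios of 1.09 and 1.88 with GSK805 and XY018 in 143B and of 1.40 and 1.0 in MG63, and NDRG1 of 1.79, 3.76, 0.93 and 1.75 in the same order. RGS9 had 1.20, 2.85, 1.62 and 0.98, PNRC1 0.98, 3.27, 1.64 and 0.96, WIPI1 1.01, 2.34, 1.05 and 0.91, and LIF 0.88, 1.86, 1.92 and 1.21. Ranked the same way downward, with size not required to reach 1.5-fold, they included PLK2 (chromosome 5, 58453982 to 58460086) and 4 genes tied to cholesterol: MVK (chromosome 12, 109573341 to 109598402), DHCR7 (chromosome 11, 71423804 to 71448393), ACAT2 and TMEM97. PLK2 had −1.74, −1.28, −1.71 and −0.85, MVK −0.83, −1.87, −1.70 and −0.83, DHCR7, short of 1.5-fold in the last, −0.66, −1.45, −1.61 and −0.56, ACAT2 −0.63, −1.93, −1.04 and −0.85, and TMEM97 −0.67, −1.72, −1.32 and −0.64. SR2211 in 143B gave between 0.19 (ARRDC3) and 0.52 (WIPI1) for the higher genes, and between −0.18 (PLK2) and 0.09 (ACAT2) for the lower ones.

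**Figure D4:**
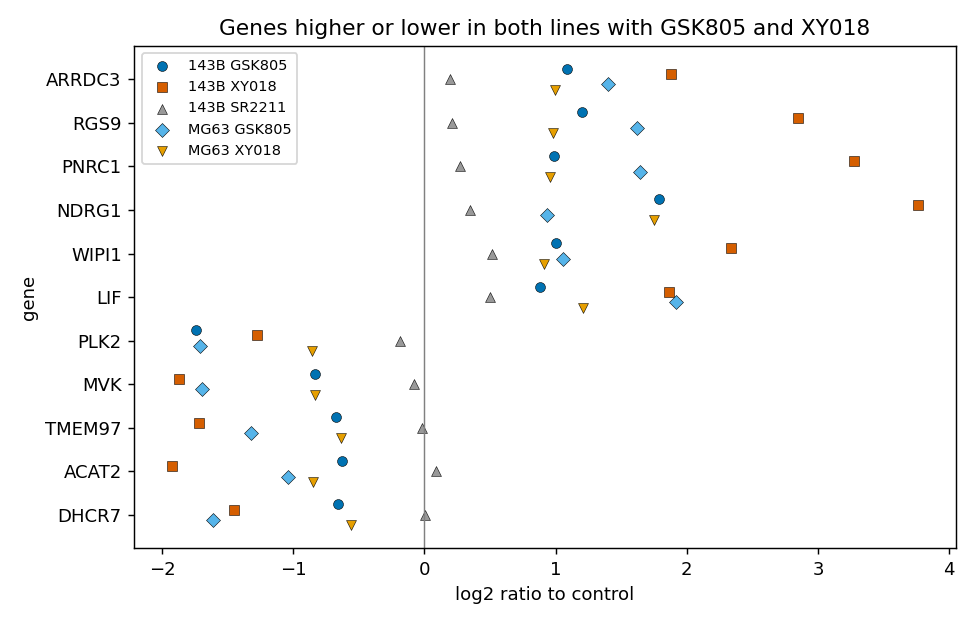
Log2 ratio to control in the 5 comparisons of genes with the largest shared difference over GSK805 and XY018 in both lines. NDRG1 reached 3.76 with XY018 in 143B, and PLK2 lay at −0.85 or below in the 4 comparisons other than SR2211.

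Of the genes of the ROR receptor family, RORA (chromosome 15, 60488284 to 61229302) had an FPKM of 1.99 in the 143B control, 3.82 with GSK805, 8.15 with XY018 and 2.13 with SR2211, log2 ratios of 0.79, 1.80 and 0.08. In MG63 it stood at 269 counts in the control, 622 with GSK805 and 334 with XY018 (1.16 and 0.32). RORB had an FPKM of 0.69 in the 143B control, 0.87 with GSK805, 1.23 with XY018 and 0.91 with SR2211, and 2.07, 5.05 and 7.62 counts in the MG63 control, with GSK805 and with XY018.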

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

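The tests of scaling, of depth and of swapped labels were chosen only after the results were seen. Those of transcript length, GC content and level, and of abundant genes, had their bounds set before they were run. The patterns they address come from these libraries, so those bounds were not set blind to the data. LXR targets had a median log2 ratio of 0.58 with GSK805 in MG63 (8 genes measured) and −0.24 in 143B (11 genes), at opposite ends of random lists. The difference between the lines was not tested. Interferon genes had 0.31 with XY018 in MG63 (35 genes measured) and −0.56 in 143B (23 genes), and that difference was not tested either. For both lists the floors admitted different members in each line, so the medians rest partly on different genes.

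The subunits of oxidative phosphorylation were lower with XY018 in 143B and with GSK805 in MG63. In 143B scaling between libraries is argued against as the whole source, since the median stayed at −0.44 under median-of-ratios scaling. In MG63 the subunits lay −0.44 from the other genes (bootstrap interval over genes −0.51 to −0.38), a distance that no factor common to all genes changes. Such a factor is therefore argued against as the whole source. The distance restates the place of the subunits among random lists and is no separate test. The size against control does depend on scaling, from −0.22 in deposited TPM to −0.44 in deposited FPKM. Against the 100 nearest genes by length, GC content and level, the subunits lay at −0.25 in 143B (interval −0.34 to −0.18) and −0.12 in MG63 (−0.18 to −0.08), where the neighbours themselves lay at −0.29 and −0.34. These intervals resample the subunits within 1 pair of libraries as if they were independent. Subunits that move together would make them too narrow, and they carry no replicate error. The neighbours were longer, with medians of 1142 bases in 143B and 1159 in MG63 against 985 for the subunits. In data simulated with a linear trend alone, this correction left means of −0.03 (SD 0.11 over draws) in 143B and −0.05 (SD 0.08) in MG63. Set before that test was run, a median difference below −0.2 was to count against these properties, with no demand on its interval. In 143B the median met that bound, but its interval did not clear it. In MG63 the median did not meet it. With the interval asked for as well, a trend with these properties cannot be told apart from a lower level of these genes in either library. In MG63 the trend may carry most of the difference. A response to the compounds, the biological explanation the design names, stays open beside it, with 1 library per group and unknown doses.

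Ribosomal protein transcripts were lower with GSK805 in MG63, with a median of −0.995. Their distance from the 100 nearest genes by length, GC content and level was −0.68, below the bound of −0.4 set before that test was run. The bootstrap interval over genes was −0.76 to −0.63. This interval, and that of the abundant genes below, treats genes as independent and carries no replicate error. The match was incomplete, since the neighbours were longer (median 1124 against 843 bases) and lower in level (8.67 against 9.46 on the log2 scale). The 200 most abundant other genes had a median of 0.0115 (−0.09 to 0.18), which argues against a lower yield of all abundant transcripts. In simulated data the same correction, with the same neighbours, left a mean of −0.04 (SD 0.11 over draws) where only a linear trend was present. A linear trend with these properties is therefore argued against as the whole source. A steeper trend among the shortest and most abundant transcripts was not simulated and stays open. A response to GSK805 in this line may account for the lower ribosomal protein transcripts, as a hypothesis found and tested on the same libraries. A difference in RNA handling of this single library stays open too.

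XY018 gave the larger response in 143B and GSK805 the larger in MG63. Depth is argued against, since the libraries of a line lay within 1.02 times of each other. The values did not settle whether labels were swapped in a single line. The mean correlation across genes between lines was 0.47 with matched labels and 0.34 with crossed ones. That difference of 0.13 (bootstrap interval over genes 0.12 to 0.15) goes with the labels as given. The ratio of GSK805 to XY018 had an r of −0.04 between lines (−0.06 to −0.01), where compounds that differ alike in both lines would give a positive value with matched labels. A shared response whose order of size differs between the lines could also give a negative value with the labels as given, so this ratio cannot decide. Both intervals rest on 1 library per group. Doses that differ between the lines could give the same order, cannot be tested here because the labels give none, and stay open beside a difference between the lines. In MG63 the ratios with GSK805 followed transcript length and GC content (Spearman 0.43 and −0.32), and those with XY018 hardly did (−0.02 and 0.07). In 143B the ratios with XY018 followed length less (0.11) than those with GSK805 (0.27). How far the trend widens the response to GSK805 in MG63 was not tested and stays open.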

How the results depend on the processing

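Counts without genes that share sequence and lists matched on length were chosen only after the data had been seen; the other alternatives were planned. No paired analysis was possible because each group held 1 library. Over 25 main counts and correlations, 227 alternative values were computed: 169 kept their value, within 1.5 times for a count, and 58 moved. Correlations across genes kept their sign under every alternative tried. Of 1894 alternative values for 244 list medians, 1890 lay within 1 SD across the list members of the main value, and 2 moved further. Of the 116 medians that stood apart, 0 changed sign under a scaling and 2 under any alternative, both as means of TGF-beta targets: −0.0447 for 143B with GSK805 (median 0.18) and −0.0161 with SR2211 (median 0.06). The lowest members, which weigh more in a mean, were CCN2 (−1.89) and TAGLN (−1.28) with GSK805 and ACTA2 (−0.78) and ID2 (−0.37) with SR2211; TAGLN and ID2 were chosen after their values were seen. Of the 128 medians that did not stand apart, 27 changed sign under a scaling and 48 under any alternative, so the direction of these is not settled. The 382 values of named genes tried were all at least 2-fold from control, so a change of sign was unlikely. Of their 2585 alternatives 2282 stayed, within 0.2 on the log2 scale, 303 moved and 0 changed sign. Named values below 2-fold were not tried. Restriction to protein-coding genes or to nuclear genes moved nothing by construction, FPKM is the main unit in 143B, and none of these was run. Where counts moved with the size asked for, the filter, the pseudocount or the genes entered, the construction shows the cause; for the other moves the cause was not tested.

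At 1.5-fold, counts of higher and lower genes were 358 and 184 for 143B with GSK805, 1780 and 2706 with XY018, 36 and 37 with SR2211, 2088 and 1641 for MG63 with GSK805 and 409 and 178 with XY018. At 4-fold they were 5 and 4, 125 and 29, 3 and 2, 78 and 18, and 8 and 2 in the same order. For the pairs, both directions together, 1.5-fold gave 3507 (143B GSK805 against XY018), 398 (GSK805 against SR2211), 4467 (XY018 against SR2211) and 3220 (MG63), and 4-fold gave 83, 5, 148 and 62.

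A pseudocount of 2 gave 22 and 10 for 143B with GSK805, 522 and 503 with XY018, 3 and 2 with SR2211 and 42 and 12 for MG63 with XY018, and 589, 21 and 985 for the 143B pairs. A pseudocount of 0.1 gave 88 and 50 for 143B with GSK805, 11 lower with SR2211 and 105 for GSK805 against SR2211. The stricter filter gave 32 and 15 for 143B with GSK805, 1 and 2 with SR2211, 45 and 11 for MG63 with XY018 and 22 for GSK805 against SR2211. No filter gave 14 and 9 for SR2211 and 48 lower for MG63 with XY018. Without genes that share sequence SR2211 had 3 higher and 1 lower. Deposited TPM gave 1068 higher and 219 lower for MG63 with GSK805, where the median of all genes lay at 0.21, and deposited FPKM gave 49 higher for MG63 with XY018.

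Between the lowest and highest alternative, lists that stood apart numbered 23 to 31 for 143B with GSK805, 24 to 33 with XY018, 10 to 18 with SR2211, 24 to 29 for MG63 with GSK805 and 23 to 26 with XY018. Depth limits what the floors leave out: in 143B values below an FPKM of 1 in both libraries, in MG63 genes below 50 counts.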

Other observations

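Every test weighed in this closing section stands in its first part; what follows are values. Xenobiotic response genes lay at opposite ends with the 2 compounds in MG63, with a median of 0.72 over 6 genes with GSK805 and −0.61 over 5 with XY018. CYP1B1, a target of the aryl hydrocarbon receptor, was at 1.6 and −1.09, and in 143B at 0.53 with GSK805, 2.66 with XY018 and 0.44 with SR2211. In 143B that list had too few measured members. PLIN2, which coats lipid droplets, was at 0.67, 3.39 and −0.05 in 143B with GSK805, XY018 and SR2211, and at −1.04 and 0.82 in MG63 with GSK805 and XY018. ANGPTL4 was at 2.61 in 143B and −1.66 in MG63 with GSK805. The pro-apoptotic gene BMF was at 0.83, 3.33 and 0.08 in 143B and at 2.93 and 1.30 in MG63, and apoptosis genes as a list had medians of 0.04, −0.24, 0.03, 0.31 and 0.16, in the order GSK805, XY018 and SR2211 in 143B, then GSK805 and XY018 in MG63.

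In that order, autophagy and lysosome genes had medians of 0.02, 0.10, 0.04, 0.43 and 0.30, with WIPI1 and the cathepsin CTSL among the genes with the largest differences in MG63, and the circadian clock had 0.18, 0.54, 0.08, 0.51 and 0.25, with NFIL3 at 1.86 with XY018 in 143B. ROR-linked nuclear receptors had 0.13, 0.35, 0.03, −0.16 and 0.01, of which the last 2 change sign with the scaling. Ferroptosis regulators had −0.09, 0.22, −0.03, 0.14 and 0.34, p53 targets 0.04, −0.21, 0.04, 0.15 and 0.10, heat shock genes −0.20, −0.45, 0.00, 0.03 and −0.12, with HSP90AA1 at −1.90 with XY018 in 143B, and fatty acid oxidation −0.05, −0.38, −0.01, −0.25 and −0.05. Fatty acid synthesis had −0.17, −0.38, 0.07, −0.28 and 0.03, mitochondrial dynamics 0.05, −0.53, −0.04, −0.07 and −0.01, sphingolipid and phospholipid genes 0.03, 0.07, 0.01, −0.06 and 0.19, and growth factor genes 0.16, 0.29, 0.05, 0.26 and −0.01. TGF-beta targets had 0.18, −0.20, 0.06, 0.24 and −0.05, YAP targets −0.29, −0.33, 0.03, −0.06 and −0.08, Wnt targets −0.23, −0.66, 0.00, 0.09 and −0.13, and junction and mesenchymal genes 0.21, 0.05, −0.02, 0.43 and −0.01.

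Bone genes had −0.06, −0.34, −0.03, 0.43 and 0.27, with TNFRSF11B at 3.0 and the phosphatase ALPL at −2.04 with GSK805 in MG63. Metallothioneins had −0.19, −0.68 and −0.11 in 143B and 0.43 with XY018 in MG63, with too few members with GSK805. Glutamine and serine metabolism had −0.09, −0.14, −0.05, −0.49 and 0.02, and G1 cyclins and CDK inhibitors 0.03, 0.12, −0.03, 0.89 and −0.03. Epithelial markers were measured in 143B alone, with medians of −0.11, −0.66 and −0.01 over 5 genes. Some of these medians change sign with the scaling. With GSK805 in MG63 they are YAP targets, mitochondrial dynamics, sphingolipid genes and ROR-linked receptors, beside glycolysis (−0.15) and the integrated stress response (−0.08). With XY018 in MG63 they are fatty acid synthesis, ROR-linked receptors, glutamine and serine metabolism and ribosomal proteins (0.03), beside complexes I, II and IV. With SR2211 they are heat shock, fatty acid oxidation, junction and mesenchymal, Wnt, sphingolipid and epithelial genes, beside hypoxia (−0.01), mitosis (−0.02), interferon genes (0.02), LXR targets (−0.02), endoplasmic reticulum chaperones (0.01), mitochondrial biogenesis (−0.003) and homologous recombination (0.01). With GSK805 in 143B they are ribosomal proteins (−0.03) alone.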
